A study of Homo sapiens with 2 samples.

How the data were processed

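Each sample was a 2-colour hybridization of total RNA from U87MG cells with stable expression of EGFRvA against U87MG cells with stable expression of EGFR, on a 35k human genome array. Per the labels' protocols, cells grew in medium with 10% serum at 37 degrees and 5% CO2, and RNA was amplified from an oligo(dT) primer through a T7 promoter and labelled after random-primed synthesis. The scanner files were deposited by the authors as spot intensity values, with foreground and local background medians, means and SDs for the Cy5 and Cy3 channels and a quality flag, per the file headers; they are not normalized. The authors' deposited value table holds log10 ratios: each value equals the scanner software's log10 ratio of Cy5 over Cy3 foreground means (largest difference 0). It was therefore on a log10 scale, without background subtraction or centring and not turned for the dye swap. Its medians were −0.221 for array 1 and −0.186 for array 2. What the negative flag (−100) stood for is not given in the sources used here; it was read as a bad-spot mark.

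The direction of each ratio was taken from the dyes in the labels, with the sign of array 2 turned. Foreground medians were background-corrected with normexp (offset 50) and normalized within each array by intensity-dependent loess in limma 3.58.1 under R 4.3.3, with control and empty spots at weight 0, and the arrays were averaged. A probe entered if it carried no bad-spot mark on either array and its foreground exceeded the local background by more than 2 background SDs on both arrays for at least 1 of the lines. Saturated spots were kept. A gene took the value of its brightest probe. Of 37632 spots in 48 print blocks, 1468 were controls or empty. Probe names came from the scanner files and were updated through a RefSeq gene table (GRCh38.p14): 18651 spots held a current symbol, 3782 an older symbol and 819 an accession found there, 3068 kept the name in the file, and 9844 had no name. No probe carried several names. Probe positions are not reported. The files were read with jsonlite 2.0.0, and figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

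In the Cy5 channel, 44.3% of probes on array 1 and 41.0% on array 2 were above background; in the Cy3 channel the shares were 23.6% and 20.2%. The arrays were treated as 1 replicate, so the calls and lists of the report rest on no p-value. Before the data were examined, a gene was set to be called when its log2 ratio was at least 1 in size with the same sign on both arrays. Also fixed then were 30 gene lists and most alternatives. Leaving bad spots out of the loess fit and centring on the measured probes were added after the data were seen. The naming rule was fixed beforehand too. The rule named the 12 highest and 12 lowest called genes, EGFR, HBEGF and STAT3, and from each list up to 2 called members at either end, or its highest and lowest member where none was called. Other list members given as examples, IGF1 among them, were chosen after their values were seen. 1 gene that the rule selects is not reported here. A list's median was placed among 10000 random lists of the same size drawn from 10 intensity classes. Where a probe was above background in a line on neither array, the fold was given as at least N-fold. It set the mean of the bright line against the higher, per array, of the dim spot and the lowest signal above background, per channel after loess and Aquantile scaling.

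The procedure was tested on simulated data for this comparison, with 200 genes changed before filtering and 5311 genes left after it. Of the changed genes that passed the filter, it called 0% of those changed 1.5-fold, 26% of those changed 2-fold and 100% of those changed 3-fold or 4-fold, and 0 of 5112 unchanged genes. A gene changed exactly 2-fold sits at the threshold, so a low share of calls there follows from the rule. The simulated noise was normal and scaled to a robust spread between the arrays, without outlying spots or differences between cultures. The simulation therefore gives no rate of false calls for the real data. Alternatives were tried for the background correction, the normalization, the spot statistic, the filters, the fold threshold, the probe summary and the source of the values, as was leaving out each array. Where the deposited ratios were the source, each array was first centred on the median of all its probes other than controls. These ratios were not tried uncentred. A limma fit that treated the arrays as samples was tried too; its adjusted p-values measure only the spread between hybridizations.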

Results

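Gene expression was compared between a pair of lines made from U87MG, an established human glioblastoma cell line. One line stably expressed EGFRvA, a form of the epidermal growth factor receptor that differs from the full-length receptor in its carboxyl-terminal part, and the other stably expressed EGFR. Total RNA of both lines was hybridized together on 2 spotted arrays, with EGFRvA cells in Cy5 on array 1 and in Cy3 on array 2. The labels name no separate cultures or extracts, so the arrays were taken as 1 comparison with the dyes swapped, and the difference has no replicate check. No U87MG line without an introduced receptor was hybridized, so a difference cannot be assigned to a change in 1 line rather than the other. Values are log2 ratios of EGFRvA over EGFR cells, averaged over both arrays, and ± gives the distance of each array from that mean (n = 1 comparison). Of 36164 probes other than controls, 6946 passed the filters on spot quality and background, and they covered 5237 named genes.

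The comparison asks which transcripts differ between cells carrying the variant and cells carrying the full-length receptor. On both arrays, 18 genes were at least 2-fold higher and 17 genes at least 2-fold lower in EGFRvA cells, together 0.668% of the measured genes. The genes called higher included PCSK2, a prohormone convertase, at 2.14 ± 0.11, and PENK, the precursor of enkephalin peptides, at 1.39 ± 0.01. Growth factor genes were also called higher: PDGFA at 1.54 ± 0.05, FGF1 at 1.5 ± 0.10 and IGF1 at 1.29 ± 0.12. The genes called lower were led by EGFR itself at −5.77 ± 0.14 and by NGFR, the low-affinity neurotrophin receptor, at −2.37 ± 0.13.

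Among the other genes called higher, TCEAL1 stood at 2.09 ± 0.49 and SRPX2, which encodes a secreted ligand of the urokinase receptor, at 1.88 ± 0.24. PLAUR, the urokinase receptor gene, was called higher as well, at 1.22 ± 0.16. PDK1, a kinase that restrains pyruvate dehydrogenase, reached 1.41 ± 0.22, the small heat shock protein gene HSPB8 1.35 ± 0.11 and OLFM1, a secreted olfactomedin, 1.32 ± 0.19. ACTR3B gave 1.55 ± 0.51, and since its spot was not above background for EGFR cells on either array it is stated as at least 2.84-fold higher. The brightest probe of the gene listed as CHP1_HUMAN gave 1.79 ± 0.07, but its second probe gave 0.03 ± 0.07. The 3 probes of PDGFA lay between 1.54 and 1.62.

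Among the genes called lower, CDH13, which encodes the membrane-anchored T-cadherin, stood at −1.75 ± 0.01, LOXL3, a lysyl oxidase, at −1.46 ± 0.005 and LGR4, a receptor for R-spondins, at −1.38 ± 0.04. ROBO1, a receptor for SLIT guidance proteins, was at −1.31 ± 0.03, while its second probe, with a bad-spot mark on 1 array, gave −0.29 ± 0.04. JDP2, a repressor in the AP-1 family, was at −1.33 ± 0.01. The metabolic genes ACAA2, a mitochondrial thiolase, and ALDH3A1, an aldehyde dehydrogenase, were at −1.48 ± 0.03 and −1.49 ± 0.02, although the second ALDH3A1 probe gave −0.11 ± 0.05. NT5DC2 gave −1.46 ± 0.31, with −1.33 ± 0.28 at its second probe, and the gene listed as Q9HD52_HUMAN gave −1.63 ± 0.23. PDGFRL had the widest gap between arrays of the called genes, with −1.02 on array 1 and −2.90 on array 2, and its mean ran from −0.995 to −3.85 over the processing settings tried. SOX2, a transcription factor of neural stem cells, and GADD45A, a p53 target, were called lower at −1.15 ± 0.01 and −1.06 ± 0.01.

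**Figure D1:**
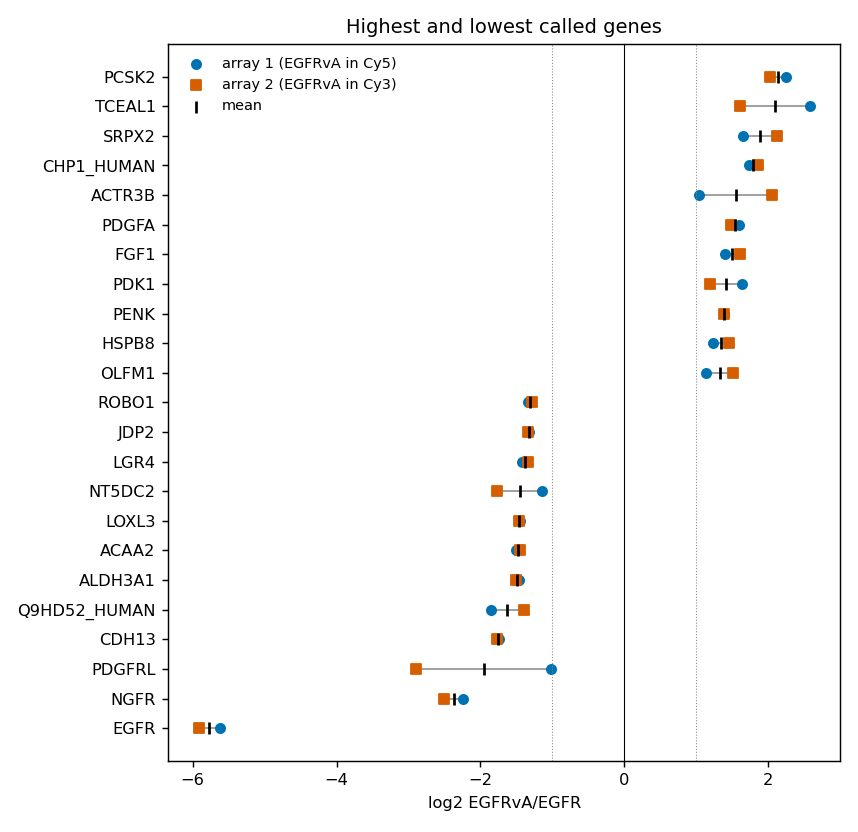
Log2 ratio of EGFRvA over EGFR cells (x axis) for the 12 lowest and all but 1 of the 12 highest called genes; circles are array 1, squares array 2 and black ticks their mean, and dotted lines mark a 2-fold difference. EGFR lies at −5.77, apart from the next lowest gene, NGFR, at −2.37, and PDGFRL shows the widest gap between arrays, from −1.02 to −2.90.

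The EGFR value came from 1 probe whose foreground signal was 54696 and 57231 for EGFR cells and 1184 and 911.5 for EGFRvA cells, a 54.6-fold difference. Both lines carry an introduced receptor gene, and the position of this probe in the transcript is not given in the sources used here, so the value does not check the labels. The 3 other EGFR probes were marked as bad spots on both arrays and none was above background on both arrays in either line. HBEGF, which encodes an EGFR ligand, and STAT3 had been chosen from knowledge of work on this receptor form and are not an independent choice. HBEGF had a bad-spot mark on 1 array and so did not enter the counts. Its log2 ratio was 1.31 ± 0.21, from a spot above background in EGFR cells on only 1 array. It was no longer at least 2-fold on both arrays without background correction (1.12) or with median centring (1.29). The same held for the deposited ratios (0.97 when centred on all probes other than controls, and 0.98 when centred on the measured probes). STAT3 was at −0.09 ± 0.14, a value smaller than the gap between the arrays.

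The hypoxia response genes stood higher in EGFRvA cells as a group. Of 10 measured members, PDK1 was called higher and none was called lower, and 8 were above 0 on both arrays. EGLN1, an oxygen-sensing hydroxylase, was at 0.91 ± 0.20, BHLHE40 at 0.90 ± 0.03 and the mitophagy gene BNIP3 at 0.78 ± 0.03, while VEGFA was at 0.004 ± 0.12 and CA12 at −0.26. The list's median was 0.51, with 0.44 on array 1 and 0.60 on array 2, at percentile 100 among 10000 random lists matched on intensity. The glycolysis genes had a median of 0.34, also at percentile 100, with no member of 8 called. Their median was lower on each array alone, at 0.25 on array 1 (percentile 99.68) and 0.27 on array 2 (percentile 99.54). ALDOA was at 0.54 ± 0.04, PFKP at 0.49 and PGAM1 at 0.44, whereas PFKM was at −0.33 ± 0.09. The middle members, which set the list's median, were GAPDH and GPI, the latter at 0.31 ± 0.03. GAPDH was at 0.38 ± 0.17 at its gene probe, but the GAPDH control spots, printed 48 times, had a median of 0.08 on each array. The list's median therefore rests in part on a gene value that these control spots did not show. These percentiles describe the arrays at hand and are not tests across cultures.

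The DNA replication and repair genes stood lower in EGFRvA cells as a group, with no member of 23 called. Their median was −0.22, with −0.24 and −0.23 on the separate arrays, at percentile 0 among the random lists, and 14 members were below 0 on both arrays against 2 above. POLA2, a subunit of DNA polymerase alpha, was at −0.60 ± 0.06, and the replicative helicase genes MCM4 and MCM3 at −0.57 and −0.44, while the mismatch repair gene MSH6 was at 0.36 ± 0.13. The mitosis and cell cycle genes had a median of 0.03 over 23 members, none called, from E2F1 at −0.35 ± 0.11 to SPC25 at 0.26 ± 0.05. The astrocyte and neural stem cell markers had a median of −0.24 at percentile 0.18. Of these 9 genes SOX2 was called lower, and GLUL and NES were at −0.50 and −0.31, while CD44 was at 0.67 ± 0.27.

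The medians of the other 26 lists lay within the central 95% of random lists. The angiogenesis and growth factor list had a median of 0.03, although 3 of its 11 members were called higher (PDGFA, FGF1 and IGF1); FGF2 was at 0.998 ± 0.12 and IGFBP7 at −0.77 ± 0.03. The ERK pathway feedback and immediate early genes had a median of 0.03 over 12 members, none called. The arrays differed, with medians of −0.06 on array 1 and 0.23 on array 2. This list's percentile of 76.58 rose above the central 95% on array 2 alone (99.66), with the deposited ratios (98.29) and with the mean of the spot pixels (98.17). DUSP6, MYC and SPRY2 were at 0.80 ± 0.20, 0.80 ± 0.13 and 0.72 ± 0.12, each at least 1.5-fold higher on both arrays, and NR4A1 was at −0.58 ± 0.14. The STAT3 target genes had a median of −0.002 over 11 members, from IRF1 at −0.26 ± 0.23 to JUNB at 0.36 ± 0.09. The list of ERBB receptors and EGF family ligands leaves out EGFR itself, and 3 of its 17 genes were measured, with a median of −0.18 and none called; TGFA was at −0.20 ± 0.05.

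Genes of the cell surface and matrix went both ways. Of 18 measured collagens and other matrix proteins (median 0.04) only LOXL3 was called, and of 7 extracellular proteases and inhibitors (median −0.02) only PLAUR. The epithelial to mesenchymal transition markers had a median of −0.02 over 12 members, with the N-cadherin gene CDH2 at −0.85 ± 0.05 and PRRX1 at 0.49 ± 0.13. The integrins and adhesion receptors had a median of −0.07 over 7 members. Receptor tyrosine kinases other than the ERBB family had a median of −0.03 over 9 members, with PDGFRA at 0.64 ± 0.04. The Notch and Wnt genes (median 0.02, 9 members) included DLL1, a Notch ligand, at 0.94 ± 0.17. The TGF-beta targets had a median of 0.02 over 6 members and the NF-kappaB targets 0.09 over 6. Apart from LOXL3 and PLAUR, none of these members was called.

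Of 14 cytosolic heat shock genes (median −0.01) only HSPB8 was called, and of 7 p53 targets (median −0.18) only GADD45A. The p53 median was −0.06 on array 1 alone (percentile 33.14) and −0.30 on array 2 alone (percentile 0.75). The endoplasmic reticulum stress and ATF4 list had a median of −0.05 over 19 members, from PSPH at −0.68 ± 0.06 to XBP1 at 0.59 ± 0.04. The medians were −0.09 for 16 cholesterol genes, 0.10 for 14 NRF2 targets, −0.04 for 3 metallothioneins and 0.03 for 55 ribosomal protein genes. They were −0.26 for 3 cytokines, −0.06 for 8 interferon-stimulated genes and −0.08 for 6 antigen presentation genes, among them PSMB10 at −0.74 ± 0.10. Markers of other cell types gave medians of −0.05 for 4 neuronal genes, −0.03 for 5 blood and endothelial genes and −0.06 for 6 epithelial genes. Apart from HSPB8 and GADD45A, no member of these lists was called.

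**Figure D2:**
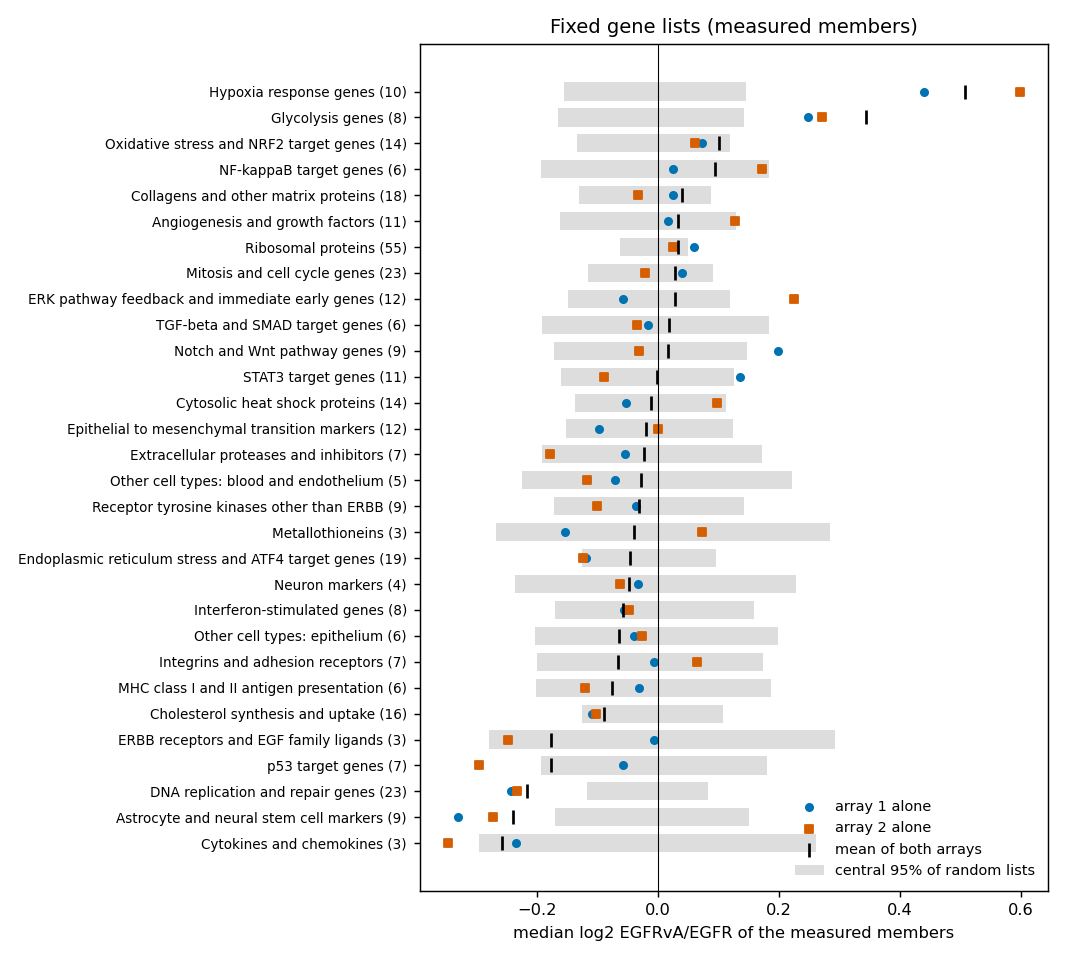
Median log2 ratio of EGFRvA over EGFR cells (x axis) for the 30 fixed gene lists, with the number of measured members in parentheses. Ticks, labelled as the mean of both arrays, are medians taken after each member was averaged over both arrays. Circles are medians on array 1 and squares medians on array 2, so a tick can lie outside both. Grey bars are the central 95% of 10000 random lists. The hypoxia (0.51) and glycolysis (0.34) lists lie above their bars, and the replication (−0.22) and astrocyte and neural stem cell (−0.24) lists below theirs.

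The log ratios of the dye-swapped arrays, both turned to EGFRvA over EGFR, correlated across the 6946 probes with Pearson r = 0.588 and Spearman correlation 0.412; probes are not independent replicates. No gene was at least 2-fold in opposite directions on the arrays, and at 1.5-fold 119 genes went the same way on both and 1 gene went opposite ways. Pearson r was 0.464 in the dimmest part of 3 equal intensity classes and 0.719 in the brightest. Of the 35 called genes, 24 were above background in both lines on both arrays. TCEAL1 and FGF1 were above background in EGFR cells on 1 array, as were HSPB8, LGR4, ROBO1, PDGFRL and Q9HD52_HUMAN in EGFRvA cells.

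**Figure D3:**
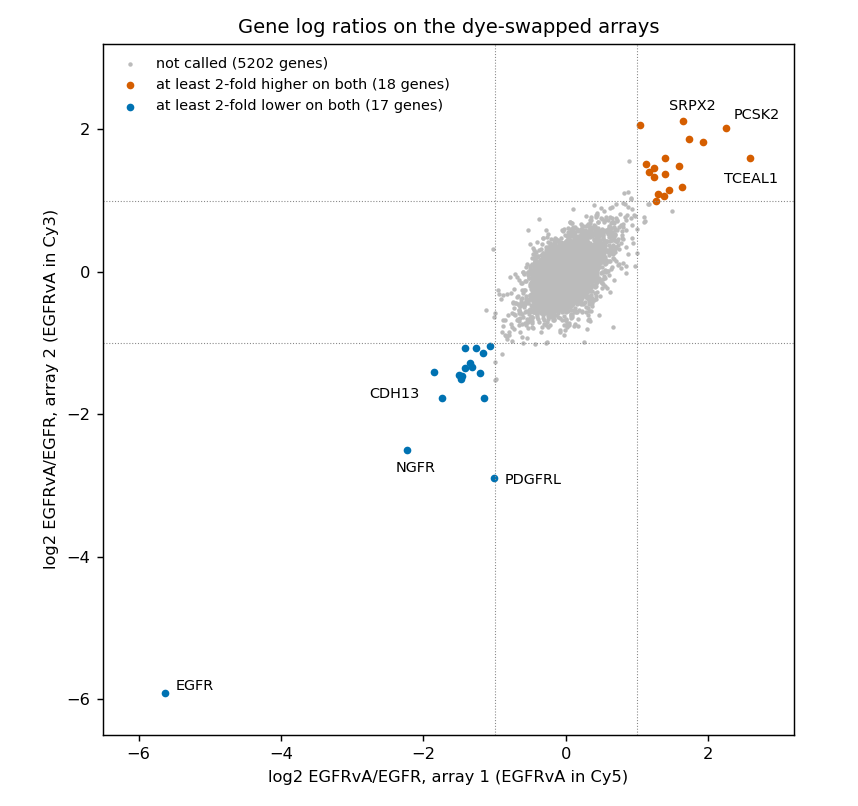
Log2 ratio of EGFRvA over EGFR cells on array 1 (x axis, EGFRvA in Cy5) and array 2 (y axis, EGFRvA in Cy3), 1 point per gene; dotted lines mark a 2-fold difference and colours the 18 genes called higher and the 17 called lower. The called genes lie in the upper right and lower left corners, and no gene lies beyond 2-fold in the upper left or lower right corner.

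The number of arrays limits the precision, and the share of bad-spot marks was 72.2% on array 1 and 77.0% on array 2, so most probes gave no value. With the deposited log ratios in place of the rescaled intensities, each array centred on all probes other than controls, 6 genes were called higher and 5 lower. The higher ones included PCSK2, TCEAL1 and SRPX2, and the lower ones were EGFR, NGFR, CDH13, ACAA2 and Q9HD52_HUMAN. Of the 24 calls that ended, 21 kept a mean of at least 2-fold, such as PENK at 1.41, PDGFA at 1.47 and FGF1 at 1.40. After this centring the medians of the measured genes lay at 0.557 and −0.577 on the arrays. The ratios were not tried as deposited, so the lost calls do not describe the authors' uncentred values. With these ratios centred on the measured probes, 13 genes were called higher and 10 lower, and 14 of the main calls still ended, 10 of them with a mean of at least 2-fold, such as PLAUR at 1.12 and SOX2 at −1.08. Median centring over all probes, with array medians of 0.250 and −0.355, ended 10 calls, all with a mean of at least 2-fold; PDK1 was then at 1.37, PENK at 1.36, PLAUR at 1.17, SOX2 at −1.19, GADD45A at −1.10, NT5DC2 at −1.51 and PDGFRL at −1.89. Centred on the measured probes instead, it gave 17 and 19 calls and ended 3 of the main ones, those of ACTR3B, FNDC3A and GADD45A, all with a mean of at least 2-fold. The mean of the spot pixels ended the call of PDGFRL, at −1.82, and the mean over probes those of ALDH3A1, at −0.80, and CHP1_HUMAN, at 0.91. The call of ACTR3B ended without background correction, at a mean of 1.30, and with both centrings on the measured probes. FNDC3A, called at 1.13 ± 0.13 with 1.001 on array 2, lost its call in 7 of 14 alternatives, among them the mean of the spot pixels and no background correction, while its mean stayed at 1.05 or above.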

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

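The tests of explanations in this part were chosen after the results were seen; the list medians on single arrays and under median centring that they draw on were planned values. The signals listed first lie in spots that the gene counts did not use.

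The spotted controls named Y1, Y2, Y3 and Y7, each printed 48 times, gave log2 ratios of EGFRvA over EGFR cells of −1.47, −1.24, −1.16 and −0.96. What these controls are is not given in the sources used here; Y4, Y5, Y6 and Y8 had at most 4 spots without a bad-spot mark on either array. The control spots for human ACTB, GAPDH and RPS9 were at −0.23, 0.08 and 0.13. Among spots with a bad-spot mark on at least 1 array, 9 named genes were at least 2-fold the same way on both arrays. They were PPARG at least 2.64-fold higher and NTN4 at least 2.08-fold higher, WNK2 at a log2 ratio of 1.38, HBEGF at 1.31, NUTM2G at −1.14, GPR37 at −1.18, PCDH9 at −1.39, PALMD at −1.67, and NACC2 at least 3.31-fold lower, named after their values were seen. Among probes with no gene name, 3 were at least 2-fold higher and 2 at least 2-fold lower on both arrays.

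The EGFR spot was 54.6-fold lower in EGFRvA cells. Dye bias would give opposite signs on the swapped arrays, but each array lay 0.144 from their mean of −5.77. A candidate explanation is that the spot reads a part of the transcript that EGFRvA lacks, and another is that EGFRvA cells hold less receptor transcript of either form. These cannot be told apart, because 0 of the 3 other EGFR probes was above background on both arrays in either line.

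The hypoxia response and glycolysis lists stood higher in EGFRvA cells. For the hypoxia list, dye bias is argued against by the medians of the swapped arrays, the lower of which was 0.44. The glycolysis medians on these arrays were 0.25 and 0.27. For the same list, the loess step is argued against as the whole cause, since under median centring the hypoxia median still exceeded that of all genes by 0.52. The glycolysis median was then 0.32, with that of all genes at −0.06. The EGFR form may account for the shift, but so may oxygen, density or medium differing between the dishes. These cannot be told apart with 1 independent comparison of the lines. Each form was also carried by 1 line only, so any other difference between the lines cannot be separated from the form.

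The DNA replication list stood lower in EGFRvA cells, with medians of −0.24 and −0.23 on the swapped arrays, which argues against dye bias. A smaller share of cycling cells was taken to lower the mitosis genes by about as much, a premise not tested here. Their median was 0.028, with a 95% bootstrap interval over members of −0.08 to 0.07, above the replication median of −0.22. The interval treats members as independent and does not cover differences between cultures. A shift between phases of the cycle and a difference in dish density may still account for the lower replication median and stay open, untested.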

How the results depend on the processing

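Leaving bad spots out of the loess fit and centring on the measured probes were chosen after seeing the data; the others were planned. The counts of 18 genes higher and 17 lower stayed within 1.5 times under all other scalings, filters and probe summaries tried than those given here, and without either array alone they ranged from 23 to 24 and from 20 to 24. With the deposited log ratios centred on all probes other than controls they were 6 and 5, each among the main calls. With these ratios centred on the measured probes they were 13 and 10, of which 13 and 8 were main calls. The offset per array left by the first centring therefore accounts for part of the loss, and the ratios were not tried uncentred. Median centring on the measured probes gave 17 and 19, of which 16 and 16 were main calls. A threshold of 1.5-fold gave 70 and 49 and one of 3-fold 5 and 3, by construction. A limma fit with the arrays as samples called 239 and 188 at an adjusted p threshold of 0.05, all 35 main calls included. The correlation of 0.588 moved to 0.614 without background correction, 0.565 with plain subtraction, 0.473 with either median centring, 0.667 with print-tip loess, 0.603 with the filter on both channels, 0.532 with bad spots kept and 0.299 with the deposited ratios however centred; the cause was not tested. EGFR stayed between −5.98 and −5.50. The 4 lists beyond the central 95% of random lists were beyond it under every alternative tried, among 8 such lists with the deposited ratios under either centring and 6 without either array. A constant offset per array cannot change the correlation or a list's percentile, so recentring the same ratios adds no separate support to either. Among 1169 other values of named genes, 41 lost the 2-fold call in the same direction, 17 of them with the deposited ratios, 9 with those ratios recentred and 8 with median centring, 1 gained it and 4 moved. Of 480 list medians, 107 moved by more than the spread of the arrays, by at most 0.20. Signal over background limits the dim genes: with both channels required above background, 12 higher and 12 lower calls were left, as fewer genes (4605) entered.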

Other observations

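The test on adjacent genes was chosen after its result was seen; the test on ribosome assembly genes was set down before its result was seen, but after the genes that prompted it. The genes named in this part were chosen after their values were seen.

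Beyond the lists, the potassium channel subunit gene KCNE4 was called higher at 1.20 ± 0.10. That call ended with median centring, at a mean of 1.12, and with the deposited ratios, at 0.99. The potassium channel gene KCNA1 was called lower at −1.31 ± 0.11, a call that ended with the deposited ratios, at −0.90. KCNE4 was above background in EGFR cells on only 1 array, and KCNA1 in EGFRvA cells on only 1 array. The hyaluronan synthase gene HAS2 was at 1.22 ± 0.34, with 0.88 on array 1 and so not called, while the hyaluronan receptor gene CD44 was at 0.67. TUBB2B, a tubulin of developing neurons, was at −1.03 ± 0.13 and the transcription factor gene NFIX at −0.77 ± 0.01. Within the lists, SERPINE2, the lowest measured member of the extracellular proteases and inhibitors, was at −0.87 ± 0.03.

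Genes for ribosome assembly appeared among those at least 1.5-fold higher in EGFRvA cells on both arrays: RPF2 at 0.78 ± 0.13, WDR12 at 0.74 ± 0.07, DCAF13 at 0.72 ± 0.004 and NIP7 at 0.72 ± 0.06. The hypothesis that such genes were higher as a class was tested on 94 other ribosome assembly genes, of which 40 were measured. Their median was 0.16, with 0.11 on array 1 and 0.19 on array 2, at percentile 100 among 10000 random lists matched on intensity. Of the 40, 22 were above 0 on both arrays and 6 below, and none was called. The highest were NOP56 at 0.60 ± 0.02, EXOSC3 at 0.57 ± 0.11 and GAR1 at 0.55 ± 0.18. The lowest were NOC2L at −0.28 ± 0.11 and POLR1C at −0.23 ± 0.02. Under the alternatives the median lay between 0.10 and 0.19. The ribosomal protein genes themselves had a median of 0.03. The assembly list's median may reflect a modest shift of such transcripts. With 1 comparison of 1 line per form, the receptor form and other differences between the lines or dishes cannot be separated.

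Large chromosome regions that differ in copy number between the lines would make the log ratios of adjacent genes alike. Over 4693 measured genes placed in order by the RefSeq table (GRCh38.p14), the Spearman correlation between adjacent genes was 0.029. In 1000 shuffles of the genes the central 95% ran from −0.028 to 0.028 and the highest value was 0.048, which put the measured value at percentile 97.7. The test did not settle whether such regions exist.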
